A study of Homo sapiens with 4 samples.

How the data were processed

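Chromatin immunoprecipitation with an antibody against H3K9me3 (Abcam) and input libraries were made from cross-linked U2OS cells, per the labels' protocols, with 2 input samples and 2 antibody samples. Nothing in the labels says whether the samples of a group came from separate cultures. Reads were handled with bcl2fastq 2.17, Trim Galore 0.6.7, Bowtie2 2.5.0 and MACS2 2.2.7.1 on the build hg19, per the submitters' processing notes, which give no role or order for these tools. The cutoff of the peak caller, the use of the input as a control, the handling of duplicate reads and the pooling of samples are not given in the sources used here.

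The deposited files were 2 broad peak lists without headers. Per the labels, both input samples name list 1 and both antibody samples name list 2, while the peaks in both lists are named as immunoprecipitations, numbered 1 and 2, so no list was given to a sample or group. Whether these numbers are replicate numbers is not given in the sources used here. The deposited fold enrichment of each peak is a ratio of signal over the peak caller's background. The deposited −log10 p and −log10 q of each peak are the authors' values too. Fold and −log10 p ranked the peaks almost identically (rho 0.9997 in list 1 and 0.9998 in list 2 for folds under 3). Folds were used to describe, rank and filter peaks within a list and to correlate overlapping pairs. A peak list carries no read count, so the depth per sample is unknown and does not enter any interval.

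Chromosomes 1 to 22 and X were used. The peaks elsewhere, 149 in list 1 and 133 in list 2, entered only the account of the highest folds and the closing section. Any peaks on Y were left out of both. Chromosome spans were taken from the last peak end, 3034.5 Mb in sum. An overlap needed at least 1 bp. Overlap was set against 1000 circular rotations of list 2 within each chromosome. Clustering was measured by the distance between neighbouring peaks and by domains of peaks less than 10 kb apart, against 100 random placements of the same widths outside peak-free stretches of at least 1 Mb, with these stretches removed from the observed chromosomes as well. Windows were 1 Mb, and the windows named are the 10 with the highest covered share in the lower of the lists. Zones of 2 Mb beside centromere gaps and chromosome ends were compared with the rest of the chromosomes, from which the longest peak-free stretches were left out. No test across replicates was possible, and percentiles describe these lists only. Shares of peaks carry Wilson 95% intervals, and small shares in the closing section carry exact ones.

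The groups, the comparisons and the main alternatives were fixed before the data were examined. The alternatives were a −log10 q of at least 2, the peaks above the median fold of their list, base pairs in both lists only, a reciprocal overlap of 50%, lists of equal length, chromosome 19 left out, windows of 100 kb, fold-weighted coverage, joining distances of 3 and 25 kb, zones of 1 and 5 Mb, and the densest windows of each list alone. Alternatives added after the data had been seen were list 1 limited to the lowest −log10 p of list 2, rotation without the peak-free stretches, shifts of 0.2 to 1 Mb, 100 rotations by peak width, the zones with the longest peak-free stretches counted as elsewhere or with all peak-free stretches of at least 1 Mb taken out, and the rank correlation of chromosomes without these stretches. The longest peak-free stretch as a stand-in for the centromere gap, and peak-free stretches of at least 1 Mb as stand-ins for assembly gaps, were also chosen after seeing the data.

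The rule for named genes asked for the 20 genes with the highest fold-weighted coverage, the best covered and the uncovered members of fixed gene lists, the genes that differed most between the lists, and 3 loci fixed by name. It was not applied, and the gene lists and gene parts that had been planned were left out, because the gene table used here is on GRCh38.p14 and its coordinates do not belong to hg19. That table served only to count zinc finger gene symbols by chromosome. Coordinates are 1-based hg19 positions.

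The overlap and clustering steps were tested on simulated data with 9000 peaks per list and 20 sets per case. Of pairs of independent lists 0% lay above the 97.5th percentile of their rotations, against 100% of pairs with part of their peaks in common. The neighbour distance of random lists was 1.001 times the random mean. The simulated peaks were placed uniformly at random, without regional differences in density. These shares therefore do not show how rotation behaves on lists that share regional density, as list 1 and list 2 do. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.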

Results

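H3K9me3, a histone mark of constitutive heterochromatin, was profiled by chromatin immunoprecipitation and sequencing in U2OS cells, an established human osteosarcoma line. The series title ties the local density of the mark to how stable genomic contacts held by HP1a condensates are, and the density of peaks along the chromosomes is therefore the quantity described here. The labels also carry the name KRAB-IDR3-TCF3, which they do not explain further. There were 2 input samples without antibody and 2 samples precipitated with an antibody against H3K9me3. The values came from 2 broad peak lists on hg19, called list 1 and list 2 below. The labels of both input samples point to list 1 and those of both antibody samples to list 2, whereas the peaks of both lists are named as immunoprecipitations, numbered 1 and 2, and no label says whether these numbers are those of the antibody replicates. Neither list was therefore assigned to a sample or group, and the lists were not compared as input against antibody. Peak lists hold no read counts, so the depth is unknown, and no value below has a replicate error.

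Peaks covered a large part of the genome in both lists. List 1 held 326674 peaks on chromosomes 1 to 22 and X, which covered 1365 Mb or 45.0% of the summed chromosome spans. List 2 held 264919 peaks, which covered 766 Mb or 25.2%. This order turned when whole peaks of list 1 under the lowest −log10 p of list 2 were dropped, which left 62093 peaks and 580 Mb. Peaks were not called anew at that limit, so the lists were still not compared at a common cutoff. The median peak width was 1973 bp in list 1 (quartiles 864 and 4715 bp) and 1564 bp in list 2 (quartiles 757 and 3373 bp), and the widest peaks were 393 kb and 255 kb. Nearly all peaks were of low enrichment. The median of the authors' fold enrichment was 1.64 in list 1 and 2.12 in list 2, the 99th percentiles were 2.42 and 3.03, and the highest folds were 279 and 298. The lists ended at different limits, with a lowest fold of 1.44 and a highest p of 0.0960 in list 1 against 1.90 and 0.0265 in list 2. A q-value at or under 0.05 was reached by 621 peaks (0.190%) of list 1 and 5488 peaks (2.07%) of list 2. A −log10 q of at least 2 was reached by 137 and 671 peaks.

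Coverage differed between chromosomes, and those covered most and least were the same in both lists. Chromosomes 20, 8, 2, 10 and 5 were covered most. Peaks of list 1 covered 58.1% of chromosome 20, 59.0% of chromosome 8, 57.1% of chromosome 2, 55.3% of chromosome 10 and 56.0% of chromosome 5. In list 2 the shares were 39.0%, 37.3%, 35.8%, 35.9% and 33.7%. The X chromosome was covered least in both lists, at 23.7% and 8.97%, and chromosome 13 was next to lowest in list 2 at 12.8% (31.2% in list 1). Chromosome 19, which is rich in genes, ranked 14 in list 1 (39.1%) and 8 in list 2 (26.2%), and 19 and 9 with peak-free stretches of at least 1 Mb taken out of the spans (41.3% and 27.7%). Spearman's rho of the covered shares over the 23 chromosomes was 0.942, and 0.834 with the same stretches taken out, a description across chromosomes that are not independent samples. With the same stretches taken out, X was covered 24.8% and 9.40%, against 61.2% and 41.0% for chromosome 20. The ratio of chromosome 20 to X was 2.45 in list 1 and 4.35 in list 2, and it was 45.3 and 252 among the peaks with −log10 q of at least 2. The covered shares were not corrected for DNA copy number, which is uneven in U2OS cells.

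**Figure D1:**
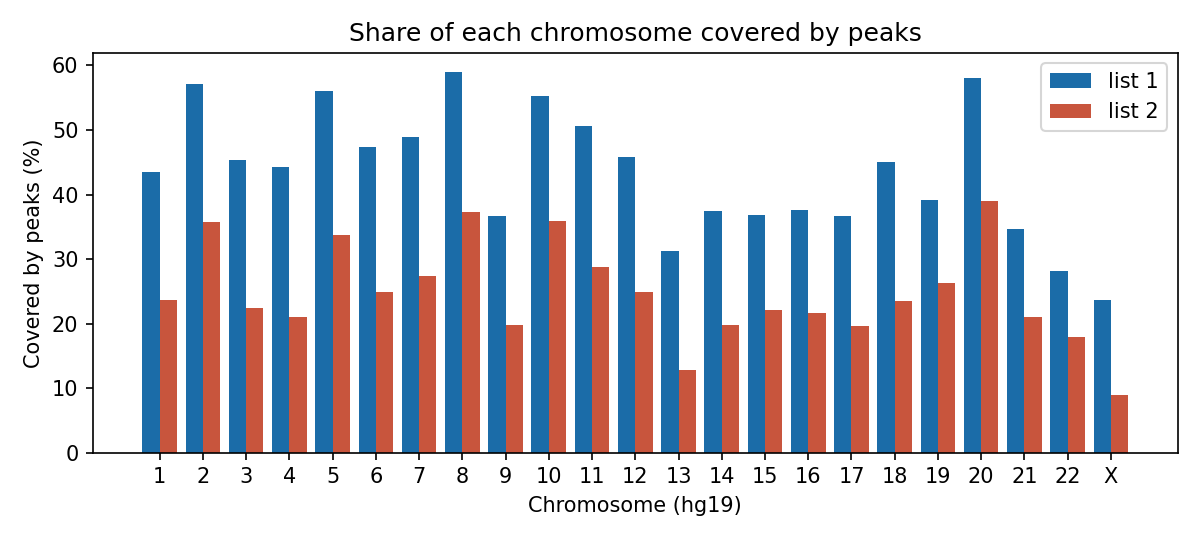
Bars show the percent of each chromosome (hg19, chromosomes 1 to 22 and X) covered by peaks of list 1 (blue) and list 2 (red), each a single value with no error. The shares of X, 23.7% and 8.97%, were the lowest in both lists.

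The densest parts of the genome were stretches of several Mb on the long arms of chromosomes 8 and 10 and near the start of chromosome 5. Among 3025 windows of 1 Mb, the median covered share was 46.2% in list 1 and 22.4% in list 2, and the 95th percentiles were 79.7% and 59.0%. The densest window, taking the lower value of the lists, was chromosome 8 from 140000001 to 141000000, at 97.4% and 91.7%. It was followed by chromosome 10 from 108000001 to 109000000, at 96.3% and 89.8%, and by the adjoining window from 109000001 to 110000000, at 96.6% and 89.4%. The other windows among the 10 densest began at 135000001 and 136000001 on chromosome 8, 107000001 on chromosome 10, 2000001 and 3000001 on chromosome 5, 37000001 on chromosome 19 and 54000001 on chromosome 20, with shares from 84.9% to 87.8% in list 2 and from 89.7% to 94.9% in list 1. None of the 10 ranked among the 10 densest when only peaks with −log10 q of at least 2 were used, and 6 did when coverage was weighted by fold.

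More than 60% of the window was covered in both lists in 142 windows. Chromosome 2 held 30 of them, chromosome 8 held 21, chromosome 10 held 16, chromosome 5 held 15 and chromosome 20 held 10, while chromosomes 1, 4, 13 and X held 0. Along chromosome 8, density rose in steps from the short arm into the distal long arm and fell again in the last windows. The mean over the 43 windows up to 43 Mb was 42.2% ± 15.9 (SD over windows) in list 1 and 20.2% ± 10.6 in list 2. Over the 71 windows from 47 Mb on, beyond the centromere, it was 62.7% ± 12.3 and 37.4% ± 12.3, and over the next 23 windows, which end with the densest window, it was 85.8% ± 7.06 and 71.9% ± 11.3. The 5 windows beyond it were covered less, with a mean of 61.8% ± 13.8 in list 1, and the last of them was covered 42.2% in list 1 and 28.6% in list 2. On the short arm of chromosome 5, the 7 windows from 2 to 9 Mb averaged 87.8% ± 6.29 and 75.3% ± 9.38, and the 37 windows from 9 to 46 Mb averaged 70.1% ± 11.9 and 47.9% ± 11.6. The segment borders were chosen after the windows had been seen.

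Chromosome 19 alternated between dense and sparse windows. The window from 37000001 to 38000000 was covered 89.7% in list 1 and 85.2% in list 2, and the window from 52 to 53 Mb was covered 87.2% and 74.7%. The 5 windows from 28 to 33 Mb, beside the centromere on the long arm, averaged 81.8% ± 5.05 and 65.5% ± 8.09. On the other side of the centromere, the 4 windows from 20 to 24 Mb averaged 30.5% ± 9.01 and 13.0% ± 5.72. The window from 11 to 12 Mb was covered 26.0% and 15.5%, and the adjoining window from 12 to 13 Mb 60.9% and 52.4%.

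**Figure D2:**
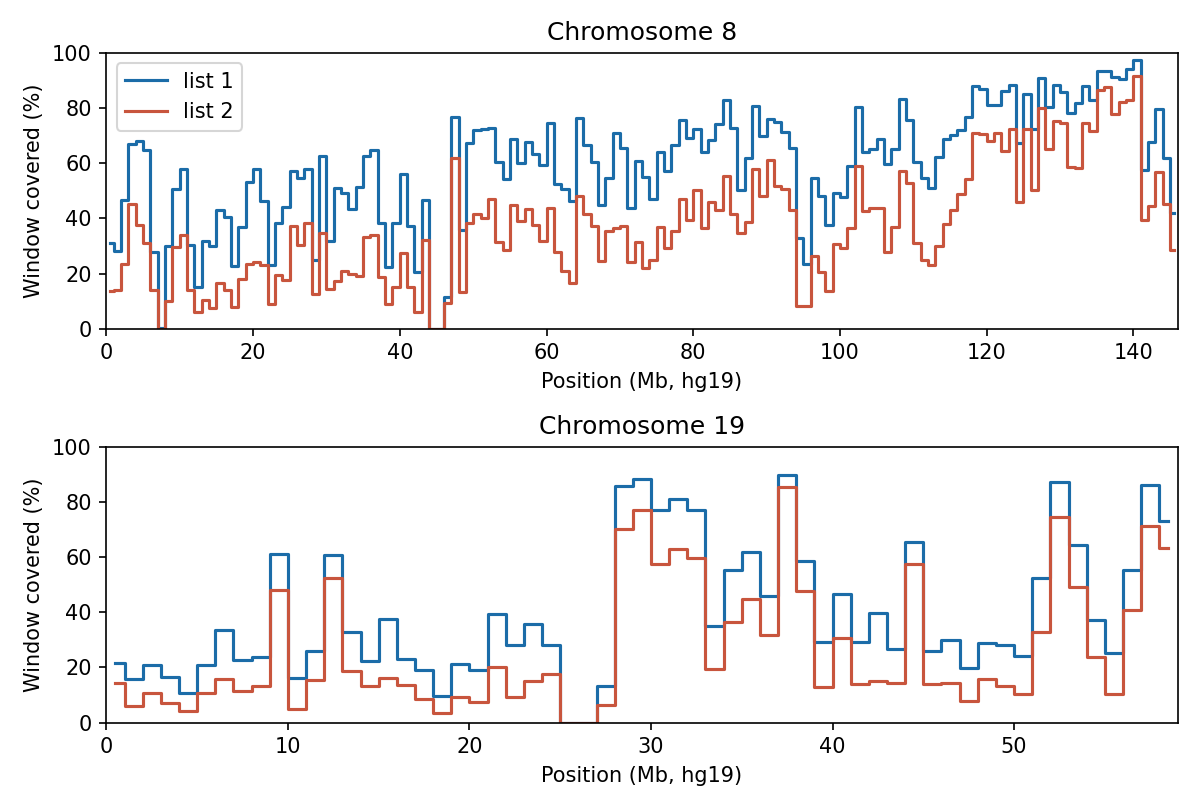
Step lines show the percent of each 1 Mb window covered by peaks (vertical axis) against position in Mb on hg19 (horizontal axis) for chromosomes 8 and 19, with list 1 in blue and list 2 in red. The lines reach 97.4% and 91.7% in the window from 140 Mb on chromosome 8.

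Peaks lay closer together than the same peaks placed at random and formed longer domains when joined under 10 kb. The median distance between neighbouring peaks was 2321 bp in list 1 against 3072 bp over 100 random placements, and 3334 bp in list 2 against 5261 bp. Peaks less than 10 kb apart joined into 27615 domains in list 1, 0.775 times the random number of 35619, and into 48273 domains in list 2, 0.671 times the random number of 71993. None of the 100 placements gave as few domains in either list. Domains of at least 100 kb held 1772 Mb in list 1 (random mean 1366 Mb) and 762 Mb in list 2 (random mean 172 Mb). The longest domain of list 1 spanned 5.76 Mb, chromosome 8 from 135706349 to 141470806. The longest of list 2 spanned 4.20 Mb, chromosome 10 from 106103906 to 110300003, where list 1 had a domain of 4.46 Mb from 105890926 to 110355684. With a joining distance of 25 kb the number of domains lay above the random number, 3.20 times in list 1 and 1.29 times in list 2, because randomly placed peaks then merged into few domains (1671 in list 1 and 11604 in list 2). Domains of at least 100 kb then held less than at random, 2491 against 2777 Mb in list 1 and 1741 against 2227 Mb in list 2.

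The lists overlapped more than by rotation, and which list had the larger share of its peaks overlapping depended on the limit of list 1. Of the peaks of list 2, 238733 (90.1%, Wilson 95% interval 90.0 to 90.2%) shared at least 1 bp with list 1, and of the peaks of list 1, 166110 (50.8%, 50.7 to 51.0%) shared at least 1 bp with list 2. The intervals cover counting error only. The shared length was 675 Mb, which was 49.5% of the covered length of list 1 and 88.2% of that of list 2. When list 2 was rotated along each chromosome 1000 times, the mean shares were 64.0% for list 2 and 44.6% for list 1. The Jaccard index of covered base pairs was 0.464, which was 2.24 times the rotated mean of 0.207 and above the highest rotated value of 0.218. Narrow peaks of list 1 were shared less often than under rotation, at 12.6% against a mean of 28.1% for those under 700 bp. Those of list 2 were shared more often, at 73.7% against 50.4%. Peaks of at least 10 kb overlapped in 99.8% (rotated mean 75.7%) of list 1 and 100% (87.8%) of list 2. When list 1 was limited to the lowest −log10 p of list 2 by dropping whole peaks, the Jaccard index was 0.436, or 3.11 times its rotated mean. By number of peaks, 34.1% of those of list 2 and 82.5% of those of list 1 then had a partner. Among peaks with −log10 q of at least 2 in both lists the shares were 13.3% and 61.3%. When at least 50% of each peak had to be shared, 19.9% of the peaks of list 2 had a partner.

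Windows ranked almost alike by density in both lists. The rank correlation of single peaks by enrichment was lower over all overlapping pairs, but it depended on how pairs were chosen. Spearman's rho of the covered share over the 3025 windows was 0.968 and Pearson's r was 0.938. Over the 238733 peaks of list 2 with a partner in list 1, rho of the fold enrichments was 0.387 and r of their log2 values was 0.45. These are correlations across windows and peaks, which are not independent replicates. They are also not directly comparable. Windows without peaks entered the correlation over windows. At most 166110 peaks of list 1 served the 238733 pairs, and part of the peaks of each list shared its lowest fold. When at least 50% of each peak had to be shared, rho of the folds was 0.574. Among peaks with −log10 q of at least 2 the order turned, as rho over windows was 0.302 and rho of the folds was 0.656.

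**Figure D3:**
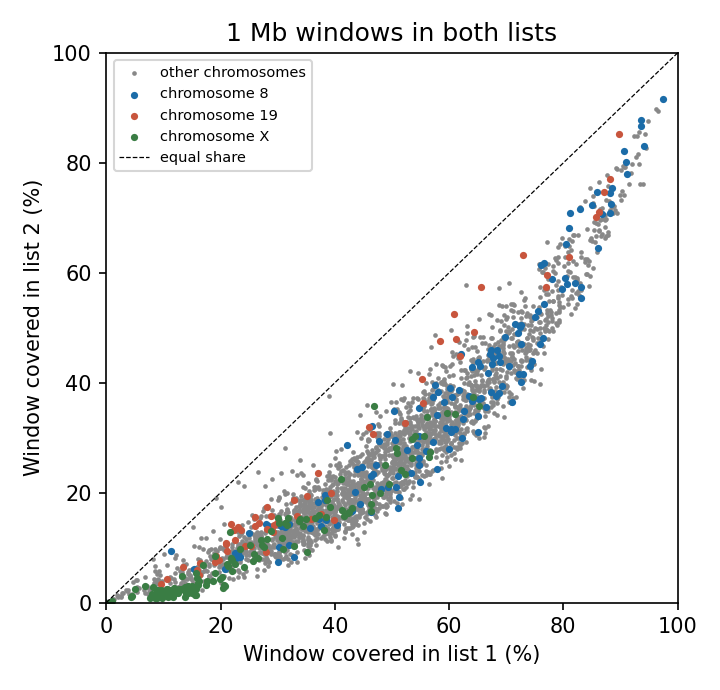
Each point is a window of 1 Mb, with the percent covered in list 1 on the horizontal axis and in list 2 on the vertical axis. Chromosomes 8, 19 and X are coloured, the dashed line marks equal shares, and rho over the 3025 windows, those without peaks included, was 0.968.

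The peaks of highest enrichment lay mostly near the long peak-free stretches around centromeres, at chromosome ends and on other contigs. The highest fold in both lists, 279 and 298, belonged to chromosome 6 from 58776164 to 58779647, beside the peak-free stretch from 58779655 to 61880216. It was followed by chromosome 7 from 61967152 to 61972674 (166 and 207), which lay 913 kb from such a stretch, and by a peak 10.0 kb from the start of chromosome 5, from 10012 to 11780 (32.3 and 29.2). Chromosome 1 from 121480999 to 121485438 (21.2 and 23.3) and chromosome 16 from 46385849 to 46414232 (16.9 and 19.9) each bordered the longest peak-free stretch of their chromosome. The last peaks of X, from 155260024 to 155260401 (6.63 and 6.65), and of chromosome 12, from 133841516 to 133841886 (6.35 and 7.53), were also among the highest. Peaks with a fold of at least 5, other contigs included and Y left out, numbered 22 in list 1 and 35 in list 2. Of these, 13 and 18 lay within 2 Mb of the longest peak-free stretch of a chromosome. In each list 3 lay within 20 kb of a chromosome end, and 5 and 11 lay on other contigs. Folds on contigs reached 19.7 and 24.1 on Un_gl000226 and 14.9 in both lists on Un_gl000220. None of these folds was corrected for repeats that the assembly holds in few copies.

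Covered length did not follow the high folds. Within 2 Mb of the longest peak-free stretches, peaks of list 1 covered 40.0% against 48.3% elsewhere with those stretches left out, a ratio of 0.828. Those of list 2 covered 26.4% against 26.9%, a ratio of 0.982 with no stable direction, which was 1.05 with the stretches counted as elsewhere and 1.01 with all peak-free stretches of at least 1 Mb taken out. Within 2 Mb of chromosome ends the shares were 39.1% and 23.8%, which were 0.808 and 0.884 times those elsewhere. In list 2 the ratio beside the stretches was also above 1 at 1.10 for the peaks above the median fold, the ratio near the ends turned to 1.03 with zones of 5 Mb, and with base pairs in both lists the ratio beside the stretches was 1.01. The direction also turned for the peaks with −log10 q of at least 2, of which 34 of 137 (24.8%) in list 1 and 71 of 671 (10.6%) in list 2 lay beside the longest peak-free stretches, a zone that made up 2.70% of the spans. Their covered share there was 28.2 and 8.03 times that elsewhere. The longest stretch without a peak stood in for the centromere gap of each chromosome, and no correction was made for repeats that the assembly holds in few copies. On chromosome 21 this stretch ran from the start to 9656386. Another peak-free stretch of 3.15 Mb began at 11186839, so the stand-in may miss the centromere gap there.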

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

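The tests on chromosome 6 in this part were chosen after the peak-free stretch had been seen, before the values they measured were known.

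Peaks on the mitochondrial genome and on alternate haplotype contigs lie outside every comparison of the results. List 1 held 5 peaks on the mitochondrial genome, with a highest fold of 3.14. List 2 held 2 there, with a highest fold of 4.17. List 2 held 1 peak on an alternate haplotype contig of chromosome 6, and list 1 held 0.

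Chromosome 6 had no peak in either list from 28477766 to 31228306 and from 31231100 to 32621024, stretches of 2.75 and 1.39 Mb. Edges were tested for a wider region, which took in most of both stretches and ran on past 32621024. In this region list 1 held 3 peaks, which covered 0.0380% of it, and list 2 held 0. A fall of H3K9me3 over an active, gene-rich region, with sloping edges, is argued against at the edges of this wider region. In both lists, the adjacent 1 Mb was covered at least 0.676 times as much as the next 5 Mb on either side. The end at 32621024 was not itself tested. A candidate explanation is the loss of reads that align equally well to alternate haplotype contigs, which hg19 also holds for regions of chromosomes 17 and 4. Placed from general knowledge of the assembly, these regions were covered at most 0.0514 times as much as the 5 Mb on either side, with 1.56% against 30.3% on chromosome 17 and 0.994% against 50.7% on chromosome 4 in list 1. No biological explanation tied to the sample groups was tested, since the lists belong to no group.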

How the results depend on the processing

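List 1 at the lowest −log10 p of list 2, rotation without peak-free stretches, shifts of 0.2 to 1 Mb, rotation by peak width and both other treatments of peak-free stretches in the zones were chosen after seeing the data. No paired analysis was possible because each peak list is 1 set of values that was assigned to no sample, and the numbers 1 and 2 in the peak names are not stated to be replicate numbers. The depth behind the lists is unknown, and few peaks passed a strict q, which limits the values at −log10 q of at least 2. The gene list and gene part alternatives were not run. The Jaccard index exceeded its rotated mean under each of the alternatives for which one was computed, from 1.81 times (shifts of 0.2 to 1 Mb) to 193 times (−log10 q of at least 2). The reciprocal overlap of 50% had no rotated mean.

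With −log10 q of at least 2, list 1 kept 137 peaks (1.43 Mb) and list 2 671 peaks (5.81 Mb), and 13.3% of the peaks of list 2 overlapped list 1. Spearman's correlation of the folds was 0.656 and that over windows 0.302, the ratio of chromosome 20 to X was 45.3 and 252, and 0 of the 10 densest windows remained. The ratio beside the longest peak-free stretches turned to 28.2 and 8.03 and that near chromosome ends to 20.6 and 4.71. Few peaks set these values, by construction.

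With the peaks above the median fold, 163345 and 132463 peaks were left by construction, 83.1% of list 2 overlapped, the ratio of chromosome 20 to X was 4.29 and 7.64, and the ratio beside the peak-free stretches of list 2 turned from 0.982 to 1.10. With base pairs in both lists, that ratio was 1.01 for list 1 and list 2 alike, and the ratio of chromosome 20 to X was 5.49. The ratio beside the stretches in list 2 was 1.05 with the longest stretches counted as elsewhere, which lowers the share elsewhere by construction, and 1.01 with all peak-free stretches of at least 1 Mb taken out. Zones of 5 Mb turned the ratio near chromosome ends in list 2 to 1.03. The cause of the other turns was not tested.

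List 1 at the lowest −log10 p of list 2 kept 62093 peaks (580 Mb), and the Jaccard index was 0.436. Of the peaks of list 2, 34.1% overlapped the peaks kept, while 82.5% of the peaks of list 1 left overlapped list 2. The overlap of list 2 was 87.5% with lists of equal length and 19.9% with 50% of each peak shared, where the correlation of the folds was 0.574. Fold-weighted coverage kept 6 of the 10 densest windows, list 1 alone kept 7 and list 2 alone kept all 10. The count for list 2 was nearly fixed by construction, since list 2 held the lower share in each of the 10. With joining under 25 kb the domain ratios turned to 3.20 and 1.29, since randomly placed peaks then merged into few domains, and the Mb in domains of at least 100 kb fell below random as well. Of the 100 densest windows of 100 kb, 26 lay inside the 10 densest windows of 1 Mb.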

Other observations

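The tests on chromosome 19, on narrow peaks and on copy number in this part were chosen after the results had been seen, and the test on zinc finger regions of other chromosomes was chosen after chromosome 19 had been seen but before the coverage of those regions was.

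Zinc finger gene clusters, which are known targets of H3K9me3 through KRAB zinc finger proteins and their partner TRIM28, were placed from general knowledge of the hg19 map, and their gene content was not checked here. Over 10 such regions outside chromosome 19, the mean covered share was 61.8% ± 17.4 (SD over regions) in list 1 and 50.8% ± 19.8 in list 2, against 49.2% and 27.3% for random regions of the same lengths on the same chromosomes. The clusters were covered 84.0% and 76.3% on the short arm of chromosome 3, 76.6% and 63.4% at the start of chromosome 4, 76.0% and 70.2% near the end of chromosome 5 and 74.6% and 63.4% near the end of chromosome 1. A cluster on the long arm of chromosome 7 went the other way, at 26.2% and 12.4% against 49.9% and 27.9% for its chromosome outside peak-free stretches. The cluster of chromosome 6, which lies beside the nearly peak-free region whose edges had been examined, was close to its chromosome, at 45.5% and 24.7% against 49.4% and 26.0%. The mean lay at percentile 98.1 of 10000 random placements in list 1 and 100 in list 2, so these clusters may be denser in H3K9me3 than their chromosomes, as a hypothesis.

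On chromosome 19, which holds 258 of 556 zinc finger gene symbols in the GRCh38.p14 gene table, the 13 windows placed on such clusters averaged 56.6% and 43.8%, against 34.2% and 21.4% for the other windows. Those other windows included the ones beginning at 25000001 and 26000001, which held no peak in either list. Neighbouring windows were more alike than distant ones. Random sets of windows were not matched for this, so percentiles among them may be too extreme. With this limit, the mean of the 13 windows lay at percentile 99.8 or above among random sets in both lists. The 4 windows from 20 to 24 Mb did not share this, at percentile 24.7 in list 1 and 12.5 in list 2, with 30.5% and 13.0% covered. Loss of reads among near-identical repeats and gene copies was not tested there. The other 9 windows averaged 68.2% and 57.4%, but the window from 11 to 12 Mb among them was covered only 26.0% and 15.5%.

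Long segments of high coverage, such as the 23 windows of the distal long arm of chromosome 8, may follow DNA copy number, since the lists hold no copy number and gained DNA raises all signal over a flat background. Differences between neighbouring windows were 0.470 times those between windows 20 Mb apart in list 2 and 0.497 times in list 1 (mean squared differences), so coverage changed over long distances. Copy number and broad H3K9me3 domains both give this and cannot be told apart from the peak lists, because input coverage was not used here.

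List 1 held 48 peaks of at most 700 bp with a fold of at least 3 and no overlap in list 2, and 22 of them (45.8%, exact 95% interval 31.4 to 60.8%) had another within 100 kb. Chance is argued against, since 10000 draws of as many narrow list 1 peaks gave a mean of 0.202 such peaks and at most 6. Copy number gain stays open. List 2 covered 11.6% of the 100 kb around them, at percentile 0.53 of the draws (mean 16.4%), but low H3K9me3 there would give the same value, so the bound set for that test could not exclude a gain. Reads from another library enriched over small targets stay open as well. Of the 30 peaks of the same kind found only in list 2, 0 had another within 100 kb (0.0%, exact upper limit 11.6%), which any cause particular to list 1 would give.

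On X, the first 2748903 bp and the stretch from 32411415 to 33665944 (1.25 Mb) held no peak in either list.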
